A study of Gallus gallus with 40 samples.

How the data were processed

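Chorioallantoic membranes of Ross 308 broiler embryos were profiled by mRNA sequencing in 40 libraries, with 10 different embryos in each of 4 groups defined by incubation day (11 or 15) and sex. Libraries were made with a NEBNext Ultra kit, per the labels' protocols. Per the submitters' processing notes, HISAT2 and HTSeq were used with the chicken genome build GRCg6a; versions, the strand setting of the counting and sequencing batches are not given in the sources used here. Genes that overlap on opposite strands therefore cannot be told apart with certainty, and members of near-identical families such as the globins, keratins and W-linked copies of Z genes may share reads.

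The authors deposited a table of 26152 gene models in 40 columns under a name for raw counts, but its values are FPKM (fragments normalised to gene length and library size). The unit was read from the values. In 15718 genes with a single transcript, 100% of the values corresponding to fewer than 200 reads were whole multiples, within 0.01, of what 1 read is worth in that library. The depth that these steps imply was 28.3 to 49.2 M reads per library (median 35.4). Whether the values were computed as FPKM or RPKM could not be settled, and both are treated alike here. The table holds 24356 Ensembl identifiers and 1796 XLOC identifiers, which have no position in the file. Symbols and coordinates were taken from the annotation columns deposited with the values, which name 13556 genes; the separate table of RefSeq names matched 0 identifiers and was not used. All 40 columns were matched to samples by name, with 0 columns left unmatched, and 0 pairs of libraries held identical values (highest pairwise correlation of log2 values 0.986). The names of a pair of columns, for a day 15 female and a day 15 male, give only the last 2 digits of the embryo numbers 102 and 100.

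Because the values are FPKM, the count model chosen before the data were examined was replaced by a test on a log scale. FPKM were scaled between libraries by an unweighted trimmed mean of log ratios (30% of log ratios and 5% of mean levels trimmed from each end) and transformed as log2(scaled FPKM + 0.1). Every fold change is on this scale, which understates the change of genes with low values. Genes with at least 0.5 FPKM in at least 10 libraries were tested, which kept 15880 genes and removed 10272. A linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with an intensity trend and robust moderation, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes at a threshold of 0.05. The contrasts were day 15 against day 11 (averaged over sexes and within each sex), male against female (averaged over days and at each day) and the sex by day interaction.

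Lists fixed before the data were examined (23 in all) covered calcium handling, the V-ATPase proton pump, acid-base transport, ion and water transport, angiogenic signalling, endothelial cells, cell cycle, innate defence, interferon response and antigen presentation, extracellular matrix, epithelial keratins and junctions, cornification, erythroid cells, leukocytes, thrombocytes, smooth muscle and mural cells, stromal fibroblasts, hypoxia and glycolysis, oxidative phosphorylation, steroid and sex hormone genes, liver and yolk sac genes, skeletal and cardiac muscle, and neural crest, glia and neurons. Each list was tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 23 lists of a contrast, and again with an estimated correlation and with fry. Members were counted over all tested genes and adjusted over the list alone. Lists of pancreatic acinar genes and of glucocorticoid-responsive genes were written later, after a first look at the data.

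Genes named in the text followed a rule fixed in advance. For the averaged day comparison it took the 8 largest increases and 8 largest decreases among genes with a symbol, a mean of at least 1 on the log2 scale and a call in the average and in each sex. For each list it took up to 4 called members with the largest change and a mean of at least 0. For the sex comparison it took up to 4 W genes, 6 Z genes higher and 3 lower in males, and 5 autosomal genes in each direction. For the interaction it took up to 5 genes in each direction. Some genes that the rule took are not printed, and some results, left out of the counts in flagged.md and sensitivity.md, are not reported here. The level thresholds had been set for log2-transformed library-scaled counts and were carried over to log2 FPKM. List members named for a sex difference, members of the glucocorticoid list, ASTL, CPA1, DMRT1 and genes singled out between 25 and 30 Mb of chromosome Z were chosen after their values were seen.

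Single values compared between groups of 10 used two-sided permutation tests with 100000 resamples (Python 3.11.15, SciPy 1.17.1, numpy 2.4.6, pandas 2.3.3). Principal components were computed on the 500 most variable genes. The procedure was tested on simulated data. For the averaged day contrast, 80.6% of simulated 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes were called among 15797 genes. The share was 68.7%, 89.6% and 97.0% for the sex difference at day 11 (15792 genes) and 49.3%, 68.7% and 95.5% for the interaction (15787 genes). False calls made up 6.70%, 9.09% and 1.39% of the calls in these simulations. Genes were simulated as independent and without structure shared among libraries, so these shares are not error rates of the real tests. A simulated list of 30 changed genes was called in 20 of 20 rounds and 0 of 440 unchanged lists were called, with genes simulated as independent.

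The alternatives changed the scaling, the filter, the pseudocount, the threshold, the samples in the fit, sample weights, covariates and the libraries and genes included. DESeq2, voom with quality weights and surrogate variables from svaseq had been chosen in advance for counts and were not run on FPKM; whole reads were examined only in genes with a single transcript. Sample quality weights on the log scale and 2 principal components of the residuals were used in their place. The number that the labels give each embryo, centred within each day and with a slope for each day, was added as a covariate, and the genes that followed it were counted by the same moderated test. In simulated data 59.7% of 1.5-fold, 80.6% of 2-fold and 90.9% of 4-fold changes between the lowest and highest number at day 11 were called among 15795 genes, with 4.94% false calls. Genes were again simulated as independent.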

Results

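The chorioallantoic membrane is the vascular membrane that lines the eggshell of a bird embryo and serves gas exchange, calcium uptake from the shell and handling of allantoic fluid. It was compared between days 11 and 15 of incubation and between male (ZZ) and female (ZW) embryos of the Ross 308 broiler, a fast-growing meat chicken. Each of the 4 groups held 10 embryos, and the 40 libraries came from different embryos. The depth implied by the values was 35.1 M reads (SD 4.0) in day 11 females, 35.4 M (SD 3.05) in day 11 males, 37.7 M (SD 5.67) in day 15 females and 35.6 M (SD 2.01) in day 15 males (means, n = 10 each). Haemoglobin genes took 4.77 ± 1.27%, 4.45 ± 0.61%, 4.25 ± 1.17% and 3.84 ± 1.54% of summed FPKM in the same order (mean ± SD).

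Libraries separated by sex and by day. Among the 500 most variable genes, of which 48 lie on chromosome W, the first principal component held 29.6% of the variance and sex accounted for 95.8% of it. The second component held 22.6%, of which day accounted for 91.9%. Over all tested genes the order changed, and the first component (29.3%) followed day. Replicate 83 of the day 15 females lay apart from the other libraries of its group toward the day 11 females.

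The day 11 libraries also differed with the number that the labels give each embryo. By limma 5103 of 15880 genes followed that number at day 11 (2540 rising and 2563 falling with it), against 0 at day 15, where 1170 had an unadjusted p below 0.05. The scaling factors of the 9 day 11 libraries numbered 2 to 20 were 0.921 to 1.00, and those of the 11 numbered 22 to 48 were 1.01 to 1.07. Both ranges held males and females. Mitochondrial genes took 9.76 to 11.1% of summed FPKM in day 11 males numbered 2 to 16 and 8.55 to 9.37% in those numbered 24 to 48, and 9.16 to 12.8% and 8.47 to 10.2% in the females of the lower and higher range. The sex comparison at day 11 gave 597 genes with embryo number as a covariate, against 552 without it. Day 15 embryos were numbered from 52 upward, so a change with embryo number between the days cannot be told apart from the change with day.

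**Figure D1:**
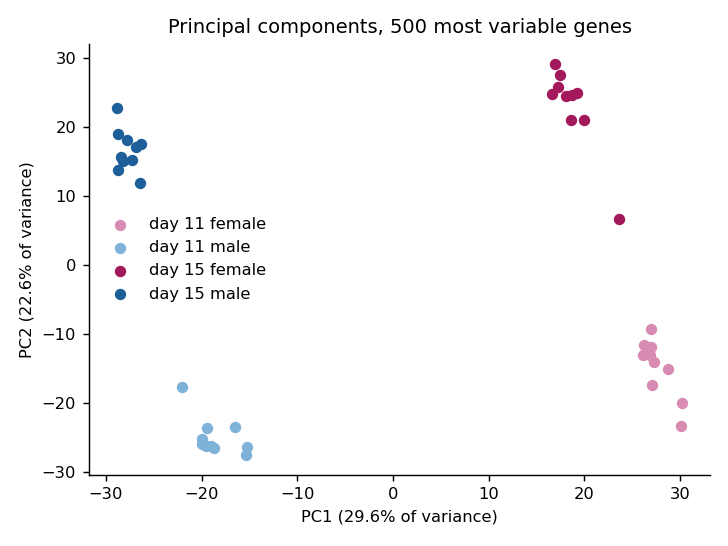
Scores of the 40 libraries on the first and second principal components of the 500 most variable genes, with 1 point per library coloured by group. The horizontal axis (29.6% of variance) separates females from males and the vertical axis (22.6%) separates day 15 from day 11.

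Between days 11 and 15 all 55 tested cell cycle genes fell, as did the embryonic globin genes HBE, HBBR and HBZ. Of the epithelial genes 26 of 37 rose, as did 16 of 21 V-ATPase, 17 of 29 acid-base transport, 12 of 21 calcium handling and 16 of 35 ion and water transport genes, but these lists lost their call with an estimated correlation (adjusted p = 0.153 to 0.285). Increases and decreases were ranked among genes with a symbol, a mean log2 level of at least 1 and a call in each sex. The largest increase was that of TGM4, a transglutaminase gene (ENSGALG00000033171, chromosome 2, 43102691 to 43113228, GRCg6a). It rose from 0.326 ± 0.167 to 57.6 ± 24.8 FPKM in females and from 0.262 ± 0.140 to 55.4 ± 25.2 FPKM in males (mean ± SD, n = 10 each). Its log2 fold change was 7.15 ± 0.20 (SE). ELOVL3, a fatty acid elongase, rose by 4.19 ± 0.25, and HSD3B1, a steroid dehydrogenase, rose by 4.0 ± 0.24. The surface protein genes PSCA and MSLN rose by 3.87 ± 0.20 and 3.53 ± 0.13. COL17A1, a hemidesmosome collagen of basal epithelial cells, rose by 3.85 ± 0.19, ISLR2 by 3.63 ± 0.22 and the adipokine gene ADIPOQ by 3.50 ± 0.14. Across these 8 genes the adjusted p was at most 1.7e-17.

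In the same ranking the largest decreases were those of the globin genes HBE, HBBR and HBZ. HBE (ENSGALG00000035309, chromosome 1, 197275578 to 197277208) fell from 172 ± 99.9 to 5.85 ± 2.73 FPKM in females and from 129 ± 45.2 to 6.36 ± 2.18 FPKM in males. The log2 fold changes were -4.57 ± 0.19 for HBE, -4.52 ± 0.19 for HBBR and -4.07 ± 0.23 for HBZ. GSTA3, a glutathione transferase gene, changed by -3.47 ± 0.19, the neuronal stathmin gene STMN2 by -3.37 ± 0.37 and the serine protease gene TMPRSS9 by -3.33 ± 0.28. APOC3, an apolipoprotein gene, changed by -2.84 ± 0.31 and RBP by -2.38 ± 0.18. For these 8 genes the adjusted p was at most 3.37e-10. In replicate 83 of the day 15 females TMPRSS9 stood at 6.97 on the log2 scale, against at most 3.27 in the other libraries of that group.

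**Figure D2:**
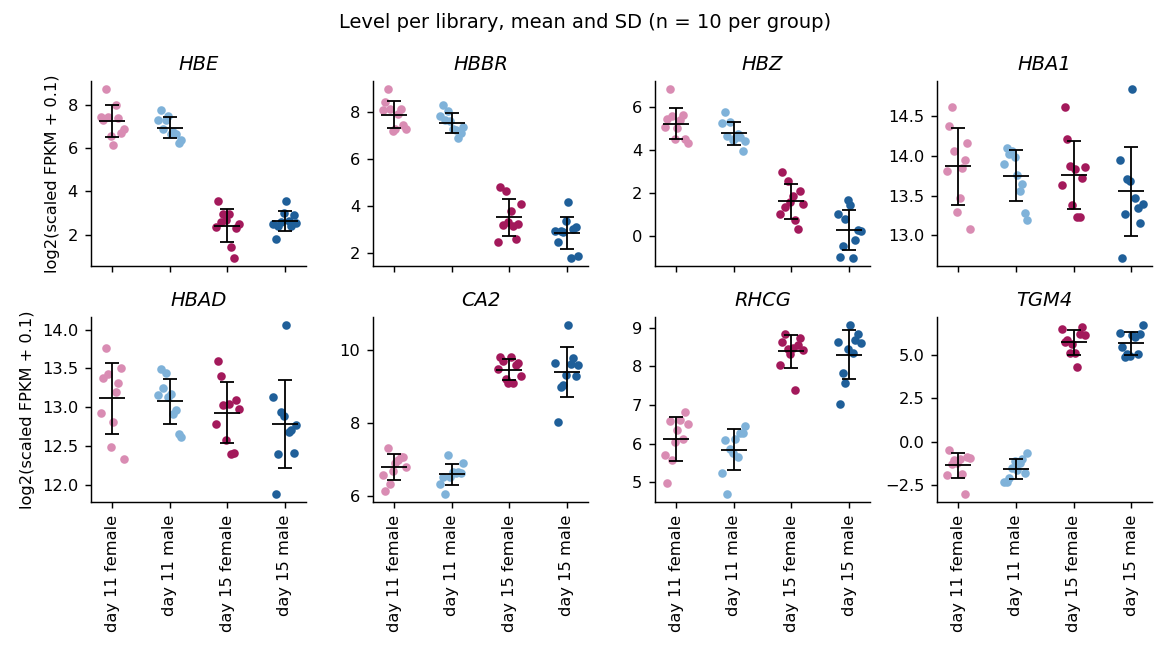
Level of 8 genes as log2(scaled FPKM + 0.1) in each library, with points for libraries and lines for the mean and SD of each group of 10. HBE, HBBR and HBZ were lower and CA2, RHCG and TGM4 higher at day 15 in both sexes, while HBA1 (adjusted p = 0.356) and HBAD (adjusted p = 0.128) did not pass the test.

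In the averaged contrast 9544 of 15880 tested genes (60.1%) differed between the days at an adjusted p below 0.05, 4811 higher and 4733 lower at day 15. A fold change of at least 2 was seen in 1347 of them, 672 higher and 675 lower, and 1439 genes differed when tested against a 1.5-fold change. Of the 23 lists, 11 were called by camera at the preset correlation, 8 upward and 3 downward. With an estimated correlation a single list, the cell cycle, held, whereas fry called 22. A list given below as not called was not called by camera. With day labels permuted within sexes, a median of 5 lists was called at the preset correlation, so that a list call at this setting is weak evidence for any single list.

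Cell cycle genes fell together. All 55 tested members were lower at day 15 and 0 were higher, with the same count adjusted over the list alone (camera adjusted p = 1.92e-45; adjusted p = 0.0389 with an estimated correlation). The mitotic kinase gene PLK1 changed by -2.03 ± 0.07, the ubiquitin-conjugating enzyme gene UBE2C by -1.93 ± 0.08, the topoisomerase gene TOP2A by -1.92 ± 0.08 and the ribonucleotide reductase gene RRM2 by -1.90 ± 0.07.

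Of 29 tested acid-base transport genes, 17 rose, 5 fell and 7 did not pass (19 and 5 adjusted over the list alone; adjusted p = 0.01; adjusted p = 0.190 with an estimated correlation). CA2, the cytosolic carbonic anhydrase, rose by 2.74 ± 0.13, from 113 ± 27 to 718 ± 137 FPKM in females and from 98.6 ± 19.9 to 743 ± 363 FPKM in males. The ammonium transporter gene RHCG rose by 2.36 ± 0.17, the sodium-proton exchanger gene SLC9A2 by 1.65 ± 0.17 and the monocarboxylate transporter gene SLC16A3 by 1.52 ± 0.15. Of 21 V-ATPase genes, which encode the proton pump, 16 rose, 1 fell and 4 did not pass (16 and 1 adjusted over the list alone; adjusted p = 0.000148; adjusted p = 0.285 with an estimated correlation). ATP6V0A4 rose by 1.30 ± 0.14, ATP6V0D2 by 1.23 ± 0.13 and ATP6V1C2 by 1.16 ± 0.11.

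Of 21 calcium handling genes, 12 rose, 3 fell and 6 did not pass (12 and 4 adjusted over the list alone; adjusted p = 0.0166; adjusted p = 0.25 with an estimated correlation). CASR, the calcium-sensing receptor gene, rose by 1.79 ± 0.18, the calcium pump gene ATP2A3 by 1.00 ± 0.07 and the calcium-binding protein gene S100A6 by 0.91 ± 0.09. Of 35 ion and water transport genes, 16 rose, 6 fell and 13 did not pass (16 and 7 adjusted over the list alone; adjusted p = 0.0166; adjusted p = 0.153 with an estimated correlation). The kinase gene SGK1 rose by 1.30 ± 0.09, the epithelial sodium channel gene SCNN1A by 1.05 ± 0.09 and ATP1B4 by 1.04 ± 0.13. The water channel gene AQP5 changed by -1.91 ± 0.46.

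Of 37 epithelial keratin and junction genes, 26 rose, 1 fell and 10 did not pass (26 and 1 adjusted over the list alone; adjusted p = 4.93e-07; adjusted p = 0.161 with an estimated correlation). KRT6A rose by 5.57 ± 0.27, KRT23 by 1.84 ± 0.11 (SE), KRT17 by 1.66 ± 0.13 and KRT14 by 1.53 ± 0.10. The cornification list was not called. Of its 10 tested genes, 3 rose, 4 fell and 3 did not pass (3 and 4 adjusted over the list alone; adjusted p = 0.601). Its median change was 0.20, while its mean was -0.25 and the test pointed downward. The protease inhibitor genes SPINK5 and CSTA changed by -1.03 ± 0.10 and -0.88 ± 0.26.

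Vascular genes moved in both directions. Of 41 angiogenic signalling genes, 19 rose, 7 fell and 15 did not pass (19 and 7 adjusted over the list alone; adjusted p = 0.0393; adjusted p = 0.361 with an estimated correlation), and with embryo number as a covariate the list was not called (adjusted p = 0.0517; range over the settings tried 1.44e-07 to 0.361). THBS2, which encodes an inhibitor of angiogenesis, rose by 1.26 ± 0.12, NOV by 0.91 ± 0.09, BMP2 by 0.75 ± 0.08 and the placental growth factor gene PGF by 0.73 ± 0.07. VEGFA, the main endothelial growth factor gene, had a log2 fold change of -0.0096 ± 0.10 (adjusted p = 0.945). Of 28 endothelial genes, 16 rose, 6 fell and 6 did not pass (16 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.0864). Without replicate 83 of the day 15 females, in which ADGRL4, ENG and BMP2 were the lowest of their group, the endothelial list was called at the preset correlation (adjusted p = 0.0169; range over the settings tried 0.00114 to 0.594) but not with an estimated correlation (adjusted p = 0.379, and 0.594 with that library). ADGRL4 rose by 0.98 ± 0.09 and ENG by 0.73 ± 0.06, whereas ESM1 and APLNR changed by -0.93 ± 0.17 and -0.76 ± 0.07. ESM1 was not called with the erythroid list score as a covariate (-0.57 ± 0.27, adjusted p = 0.0910, range over the settings tried 2.61e-06 to 0.214). That score contains HBE, HBBR and HBZ and itself fell with day, from a mean of 0.383 to -0.256 in females and 0.308 to -0.435 in males. As a covariate it takes out part of the change with day, so a call lost with it does not separate red-cell content from day.

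Smooth muscle and mural cell genes rose in 18 of 24 tested members, fell in 5 and did not pass in 1 (18 and 5 adjusted over the list alone; adjusted p = 0.00742; adjusted p = 0.361 with an estimated correlation). RGS5, a pericyte gene, rose by 1.55 ± 0.22 and the calponin gene CNN1 by 1.31 ± 0.22 (SE); both were highest among day 15 females in replicate 83. With the erythroid list score, which itself fell with day, as a covariate CNN1 was at 0.52 ± 0.33 and not called (adjusted p = 0.207, range over the settings tried 2.66e-08 to 0.207). Skeletal and cardiac muscle genes were not called as a list, with 5 of 12 higher, 3 lower and 4 not called (5 and 3 adjusted over the list alone; adjusted p = 0.553). Among them ACTA1, an alpha-actin gene, rose by 1.45 ± 0.21 and was likewise highest in replicate 83; with that covariate it was at 0.72 ± 0.32 and not called (adjusted p = 0.0661; range over the settings tried 4.64e-10 to 0.0661). Stromal fibroblast genes fell in 18 of 24 tested members, rose in 2 and did not pass in 4 (2 and 18 adjusted over the list alone; adjusted p = 0.00907; adjusted p = 0.190 with an estimated correlation). The transcription factor genes HAND1 and TWIST2 changed by -0.99 ± 0.07 and -0.90 ± 0.08, while PRRX2 and THY1 rose by 1.98 ± 0.16 and 1.04 ± 0.08. Extracellular matrix genes went both ways, with 19 of 51 higher, 15 lower and 17 not called (19 and 15 adjusted over the list alone; adjusted p = 0.263). FMOD rose by 1.93 ± 0.11, TNC by 1.87 ± 0.14, COL8A1 by 1.84 ± 0.14 and LOXL1 by 1.55 ± 0.07.

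Leukocyte genes fell in 24 of 37 tested members, rose in 8 and did not pass in 5 (9 and 24 adjusted over the list alone; adjusted p = 0.000773; adjusted p = 0.361 with an estimated correlation). The macrophage genes TIMD4, MARCO and CSF1R changed by -2.63 ± 0.20, -1.88 ± 0.31 and -1.44 ± 0.10, and the myeloid transcription factor gene SPI1 by -1.70 ± 0.13. Innate defence genes were not called as a list, with 18 of 37 higher, 7 lower and 12 not called (18 and 7 adjusted over the list alone; adjusted p = 0.110). PTGS2, the inducible cyclooxygenase gene, rose by 1.88 ± 0.12 and IL6 by 1.27 ± 0.12, while TLR4 and TF changed by -1.36 ± 0.14 and -1.35 ± 0.19. Interferon and antigen presentation genes were not called either, with 12 of 30 higher, 4 lower and 14 not called (12 and 4 adjusted over the list alone; adjusted p = 0.110). The class I genes BF1 and BF2 rose by 0.86 ± 0.09 and 0.75 ± 0.15, and IRF1 rose by 0.55 ± 0.05.

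Among blood genes, the erythroid list was not called, with 3 of 19 higher, 6 lower and 10 not called (3 and 6 adjusted over the list alone; adjusted p = 0.110). The abundant globin genes HBA1 and HBAD had log2 fold changes of -0.15 ± 0.14 (adjusted p = 0.356) and -0.24 ± 0.13 (adjusted p = 0.128), and the gene the annotation names HBE1 had -0.32 ± 0.22 (adjusted p = 0.225). With the erythroid list score as a covariate, HBA1 and HBAD changed direction and were called (0.86 and 0.79); that score contains the globins that fell. BPGM, which makes the red-cell effector bisphosphoglycerate, rose by 1.56 ± 0.10. Thrombocyte genes were not called, with 7 of 15 higher, 1 lower and 7 not called (7 and 1 adjusted over the list alone; adjusted p = 0.133). GP9 rose by 0.84 ± 0.16 and F13A1 changed by -1.03 ± 0.10.

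Hypoxia and glycolysis genes rose in 20 of 35 tested members, fell in 7 and did not pass in 8 (20 and 7 adjusted over the list alone; adjusted p = 0.00907; adjusted p = 0.153 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase gene, rose by 1.66 ± 0.11, the glycolytic regulator gene PFKFB3 by 1.56 ± 0.15, DDIT4 by 1.19 ± 0.08 and BNIP3 by 0.99 ± 0.07. Oxidative phosphorylation genes were not called as a list, with 16 of 59 higher, 5 lower and 38 not called (12 and 5 adjusted over the list alone; adjusted p = 0.545). UQCRC1 rose by 0.50 ± 0.04 (SE) and ATP5G3 changed by -0.40 ± 0.06. When the erythroid list score, which itself fell with day, was a covariate, ATP5G3 changed by -0.20 ± 0.09 without a call (adjusted p = 0.0699, range over the settings tried 1.71e-14 to 1). Steroid and sex hormone genes were not called, with 15 of 35 higher, 9 lower and 11 not called (15 and 9 adjusted over the list alone; adjusted p = 0.202). The steroid reductase gene SRD5A2 rose by 3.38 ± 0.22 and the nuclear receptor gene NR0B1 by 2.06 ± 0.14. DIO2, which activates thyroid hormone, changed by -2.08 ± 0.20.

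Among tissues that could have been collected with the membrane, the liver and yolk sac, the neural and the skeletal and cardiac muscle lists were not called by camera. Blood cell lists are given above, of which leukocytes were called at the preset correlation. By fry, liver and yolk sac genes (adjusted p = 1.87e-05) and neural crest, glia and neuron genes (adjusted p = 8.21e-07) were called. So were skeletal and cardiac muscle genes (fry adjusted p = 0.0285). Liver and yolk sac genes were higher in 3 of 14, lower in 7 and not called in 4 (4 and 8 adjusted over the list alone; adjusted p = 0.205), and APOA1 changed by -1.54 ± 0.21. Neural crest, glia and neuron genes were higher in 1 of 10, lower in 5 and not called in 4 (2 and 5 adjusted over the list alone; adjusted p = 0.210), and PRPH changed by -1.85 ± 0.16. APOA1, DIO2, CSTA, TNC, SPI1 and SLC16A3 were highest, and CASR lowest, among day 15 females in replicate 83. Without that library 9595 genes were called between the days, 9311 of them among the 9544 called with it.

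**Figure D3:**
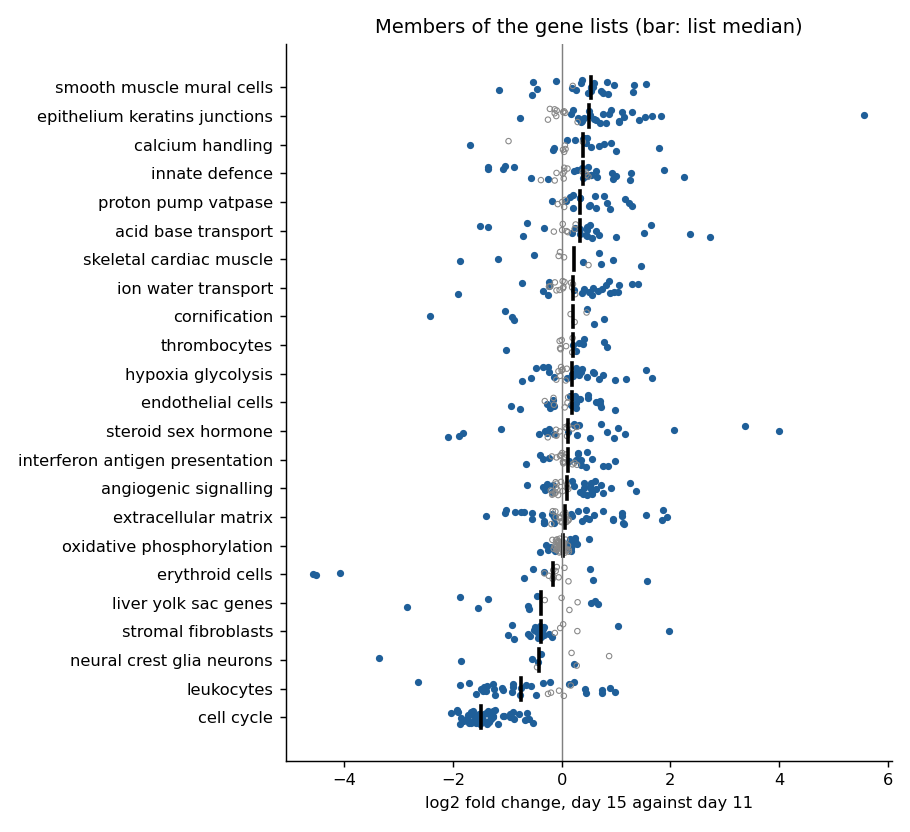
Log2 fold change between day 15 and day 11 for the tested members of the 23 lists, with 1 point per gene (filled, adjusted p below 0.05; open, at or above) and a bar at each list's median. All 55 cell cycle genes lie to the left of 0, and 26 of 37 epithelial keratin and junction genes are filled and to the right of it.

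The change with day was compared between the sexes. In males 7573 genes differed between the days (3815 higher and 3758 lower at day 15) and in females 7250 (3633 and 3617). Of these, 6072 were called in both sexes, all in the same direction, where independent lists would share 3457. Of the shared genes 3051 rose, against 873 for independent lists, and 3021 fell, against 856. The fold changes in the sexes, which come from different libraries, correlated across genes with r = 0.902 and rho = 0.867, and 86.3% had the same sign. Genes are not independent replicates.

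The sex by day interaction was called for 4 genes (3 positive, 1 negative), and 504 genes had an unadjusted p below 0.05. The number was 8 without a filter or with a pseudocount of 1, and 2 with the library of lowest depth in each group left out. TMOD1, a Z-linked tropomodulin gene (ENSGALG00000002125, 70995461 to 71015584), was at 6.88 ± 1.07 FPKM in females and 12.8 ± 1.24 in males at day 11. At day 15 it was at 3.87 ± 0.26 and 12.2 ± 1.96, with an interaction of 0.72 ± 0.12 (SE; adjusted p = 0.00322). ENSGALG00000048050, at 26172920 to 26177361 on chromosome Z, rose from 2.27 ± 1.31 to 8.99 ± 3.84 FPKM in females and was at 2.72 ± 0.55 and 2.54 ± 1.85 in males (interaction -2.30 ± 0.41, adjusted p = 0.00882). It was not called with those libraries left out (adjusted p = 0.0698; range over the settings tried 0.000205 to 0.601). XLOC_027758 and XLOC_027788 have no position in the file and were listed at 0 in all 20 male libraries. In females their levels went from 3.25 ± 1.01 to 0.612 ± 0.336 and from 0.952 ± 0.50 to 0.255 ± 0.147 FPKM. The second, with an interaction of 1.57 ± 0.31, was not called without replicate 83 of the day 15 females (1.52, adjusted p = 0.0781). Nor was it called with embryo number (1.57, adjusted p = 0.0704) or the erythroid list score (1.56, adjusted p = 0.0606) as a covariate (range over the settings tried 0.00338 to 1). At the preset correlation camera called the cell cycle (adjusted p = 0.0180) and oxidative phosphorylation (adjusted p = 0.0290) lists for the interaction. With an estimated correlation each had an adjusted p of 0.964, and 0 of their members were called by limma. Without replicate 83 of the day 15 females, oxidative phosphorylation was not called (adjusted p = 0.135), whereas the endothelial (adjusted p = 0.0172) and epithelial (adjusted p = 0.0158) lists were at the preset correlation only (adjusted p = 0.717 each with an estimated correlation).

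Males and females differed mainly in genes of the sex chromosomes. Averaged over days, 769 genes differed, 540 higher and 229 lower in males. Of these, 465 lie on chromosome Z, 49 on W and 192 on autosomes, and 63 have no position on a named chromosome. At day 11 552 genes differed (403 higher in males) and at day 15 556 (411 higher). The 676 tested Z genes had a median log2 difference of 0.48 (quartiles 0.21 and 0.71), a 1.40-fold excess in males (0.25 without a filter on low values), and 442 were called higher in males and 23 lower. The autosomal median was -0.018. The camera p with an estimated correlation was 1.77e-19 for Z and 1.14e-21 for W.

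Per library, the median Z level relative to autosomes was -0.25 ± 0.05 in females and 0.24 ± 0.06 in males at day 11, and -0.22 ± 0.05 and 0.24 ± 0.03 at day 15 (log2, mean ± SD, n = 10 each). The sexes did not overlap at either day. At day 11 males numbered 2 to 16 stood at 0.15 to 0.23 and those numbered 24 to 48 at 0.27 to 0.31, and females numbered 3 to 20 at -0.33 to -0.21 and those numbered 22 to 46 at -0.24 to -0.19. The differences of 0.49 and 0.45 each had a two-sided permutation p of 2e-05, the smallest the resamples can give (adjusted over both days, 2e-05). W genes held 0.344 ± 0.012% of summed FPKM in females and 0.0014 ± 0.00058% in males at day 11, and 0.257 ± 0.019% and 0.0011 ± 0.00033% at day 15. All 40 libraries thus matched their sex labels.

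All 49 tested W genes were called, 48 of them lower in males. HINTW, the W-linked copy of a histidine triad gene (ENSGALG00000035998, 1840623 to 1896773), was at 1169 ± 172 and 738 ± 102.4 FPKM in females of days 11 and 15, against 1.72 ± 1.73 and 1.18 ± 0.96 in males. HNRNPKL was at 66.5 ± 4.78 and 52.3 ± 5.26 FPKM in females and at most 0.10 ± 0.096 in males. SPIN1W was at 14.9 ± 1.52 and 14 ± 1.60, and the W gene the annotation names UBAP2 at 13.5 ± 1.18 and 12.9 ± 1.30, with male means of at most 0.023. ENSGALG00000047434 (W, 3570685 to 3580610) was the exception and was higher in males by 0.65 ± 0.09.

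On chromosome Z the excess in males was 1.25 ± 0.06 (log2, SE) for TMOD1, 1.10 ± 0.11 for TMC1, 1.10 ± 0.08 for the cyclophilin gene PPIC and 1.08 ± 0.17 for the acetylcholine receptor gene CHRNA6. RLN3, a relaxin gene (27624861 to 27627531), was lower in males by -1.04 ± 0.20, the synaptic scaffold gene HOMER1 (22241850 to 22331531) by -0.95 ± 0.15 and the glutamate transporter gene SLC1A1 (27065681 to 27123343) by -0.81 ± 0.14. For these 7 genes the adjusted p was at most 0.000263. The 23 Z genes higher in females were unevenly placed, with 12 of the 40 tested genes between 25 and 30 Mb and 11 of the 636 elsewhere. Of those 11, 6 lay in the adjoining stretch between 20 and 25 Mb, among its 68 tested genes.

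**Figure D4:**
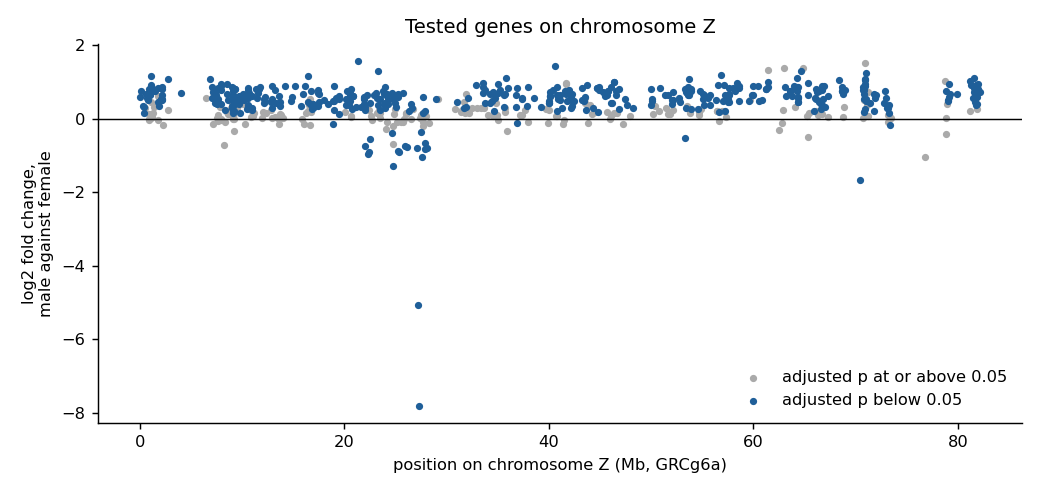
Male against female log2 fold change of the 676 tested chromosome Z genes by position (Mb, GRCg6a), with 1 point per gene (blue, adjusted p below 0.05; grey, at or above). Most genes lie above 0 (median 0.48), and 12 of the 23 genes called higher in females lie between 25 and 30 Mb.

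Autosomal differences between the sexes were few and small. Of 13950 tested autosomal genes 192 differed, 64 higher and 128 lower in males, and 2 of them by at least 2-fold. The excess of lower genes depended on the scaling, since 99 were higher and 92 lower with factors from autosomal genes, and 72 and 94 without scaling. The number was 79 at an adjusted p below 0.01, 0 against a 1.5-fold change and 591 with 2 residual components as covariates. Higher in males were the transcription factor gene PAX1 (0.82 ± 0.20), the cannabinoid receptor gene CNR1 (0.54 ± 0.15), the platelet glycoprotein genes GP9 (0.51 ± 0.16) and ITGA2B (0.50 ± 0.11), and the collagen gene COL2A1 (0.51 ± 0.13). Lower in males were HBZ (-0.89 ± 0.23), GTSF1 (-0.76 ± 0.14), the complement gene C1QA (-0.62 ± 0.16), GRIK1 (-0.56 ± 0.15) and the chemokine receptor gene CCR7 (-0.50 ± 0.15). The adjusted p was at most 0.0455. GP9 and CCR7 were not called without replicate 83 of the day 15 females (adjusted p = 0.0563 each), with differences of 0.51 and -0.46. With the library of lowest depth in each group left out, their adjusted p was 0.230 and 0.0650, with differences of 0.41 and -0.49. Over the settings tried it ranged from 0.00499 for GP9 and 0.0138 for CCR7 to 1 for both, the highest against a 1.5-fold change.

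Called autosomal sex differences were shared between the days more often than independent lists would be, while fold changes over all autosomal genes correlated weakly. At day 11 75 autosomal genes were called and at day 15 77, with 17 called at both in the same direction, where 0.414 would be expected for independent lists. Across autosomal genes, most of which were not called, the fold changes of the days correlated with r = 0.125 and rho = 0.232. Across Z genes r was 0.880 and rho 0.842. The sex by day interaction was called for 0 autosomal genes.

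Of the 23 lists, 4 were called between the sexes at the preset correlation, and 0 with an estimated one. Permuted sex labels gave as many list calls in 78 of 100 splits. Extracellular matrix genes were higher in males in 6 of 51 members and lower in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.00158; adjusted p = 0.819 with an estimated correlation), among them the Z-linked fibrillin gene FBN2 (0.49 ± 0.09), MFAP5 (0.45 ± 0.11) and the collagen gene COL1A1 (0.27 ± 0.08). COL1A1 was not called with the library of lowest depth in each group left out (adjusted p = 0.126), nor with the erythroid list score as a covariate (adjusted p = 0.0767; range over the settings tried 0.0201 to 1). Thrombocyte genes were higher in males in 4 of 15 members and lower in 0 (5 and 0 adjusted over the list alone; adjusted p = 0.0234; adjusted p = 0.791 with an estimated correlation). Among these were GP9, ITGA2B and the purine receptor gene P2RX1 (0.46 ± 0.10). Epithelial genes were lower in males in 1 of 37 members, OVOL2 (-0.30 ± 0.07), and higher in 0 (0 and 5 adjusted over the list alone; adjusted p = 0.00116; adjusted p = 0.819 with an estimated correlation). V-ATPase genes were lower in males in 1 of 21 members, ATP6V1B2 (-0.14 ± 0.03), and higher in 0 (0 and 1 adjusted over the list alone; adjusted p = 0.0353; adjusted p = 0.819 with an estimated correlation). The smallest adjusted p among the other lists was 0.133.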

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

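The tests of the globin pattern, of pancreatic tissue and developmental stage for the ASTL pattern, of the thrombocyte pattern and of embryo number were chosen only after the results were seen.

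Within each group of 10 libraries, the gap of the highest or lowest library to its neighbour, divided by the group's range, was compared with Dixon's critical value for groups of 10. Of 512 combinations of a value and a group, 49 exceeded it, where chance would give 25.6. Replicate 83 of the day 15 females held 16 of the 49, and no other library held more than 4. It was highest of its group for TMPRSS9 (ratio 0.661), SLC16A3 (0.648), TNC (0.566), CSTA (0.703), SPI1 (0.490), RGS5 (0.502), CNN1 (0.583), DIO2 (0.779), APOA1 (0.609), ACTA1 (0.512) and CPA1 (0.544). It was lowest for CASR (0.630), BMP2 (0.738), ADGRL4 (0.619), ENG (0.621) and the share of FPKM on chromosome W (0.528), which was 0.212% against 0.245% in the next library.

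In day 11 females, replicate 11 was highest for HBZ (0.484) and UQCRC1 (0.541) and lowest for CNN1 (0.492) and ACTA1 (0.511). Replicate 6 was highest for AQP5 (0.482) and DDIT4 (0.569) and lowest for SCNN1A (0.536) and FBN2 (0.531). Single libraries of that group stood apart for BF1 (replicate 29, high, 0.511), MARCO (replicate 26, low, 0.591), FKBP5 (replicate 20, low, 0.520) and XLOC_027758 (replicate 22, low, 0.503). In day 11 males these were ISLR2 (replicate 2, low, 0.506), AQP5 (replicate 16, high, 0.472), PGF (replicate 38, low, 0.468), DDIT4 (replicate 7, high, 0.657), NR0B1 (replicate 24, low, 0.520) and ENSGALG00000048050 (replicate 9, low, 0.475). In day 15 females replicate 74 was highest for THY1 (0.501) and COL2A1 (0.505) and replicate 54 for BF1 (0.489).

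In day 15 males replicate 93 was highest for the class I genes BF1 (0.569) and BF2 (0.650). Replicate 52 was lowest for NOV (0.549) and CNN1 (0.514), and replicate 81 for THBS2 (0.588) and FBN2 (0.513). Replicate 98 was lowest for TIMD4 (0.517) and PRPH (0.581) and highest for ENSGALG00000050012 (0.685). Replicate 57 was lowest for SLC9A2 (0.480), replicate 100 for TMC1 (0.477) and replicate 67 for RLN3 (0.493).

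The change with day differed between the sexes, by the interaction term, for TMOD1 (0.72), ENSGALG00000048050 (-2.30), XLOC_027758 (2.35) and XLOC_027788 (1.57). The XLOC pair was listed at 0 in all 20 males, so its interaction reflects the fall in females alone. By camera at the preset correlation it differed for the cell cycle (adjusted p = 0.0180) and oxidative phosphorylation (adjusted p = 0.0290) lists. Neither call held with an estimated correlation (adjusted p = 0.964 each) or by fry (adjusted p = 0.950 each), and without replicate 83 of the day 15 females oxidative phosphorylation was not called (adjusted p = 0.135; range over the settings tried 0.00483 to 0.964).

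HBE, HBBR and HBZ fell by over 4 on the log2 scale while the abundant HBA1 and HBAD did not pass the test. Fewer red cells at day 15 would lower all erythroid genes alike, but the other 16 erythroid list members had a median change of -0.13 (quartiles -0.26 and 0.071). Scaling between libraries was too small to produce a fall of this size, with factors of 0.921 to 1.07. The smallest fall of the 3 globins over the scaling alternatives was 4.07, an outcome that factors so near each other fixed in advance. A switch of the red cells from embryonic to later globins with incubation day may underlie the pattern, a hypothesis that was not tested apart from these data.

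ASTL, an astacin protease gene, and the carboxypeptidase gene CPA1 varied together between libraries of the same group, and residuals within groups correlated with r = 0.883 and rho = 0.851 (n = 40, adjusted over the 3 relations computed, permutation p = 1e-05 for each coefficient, the smallest the resamples can give, adjusted p = 1.5e-05), and without the 2 libraries farthest from the median r was 0.849. Pancreas collected with replicate 83 is argued against, since 16 other pancreatic genes differed there from the other day 15 females by a median of -0.053 (range -1.09 to 2.19, highest for AMY2A at 41 FPKM; AMY1A was at 31.5), and so is library depth, which ASTL did not follow (r = 0.0057, rho = 0.082, permutation p = 0.971 and 0.612, adjusted p = 0.971 and 0.612; r = 0.171 without the 2 farthest libraries). An earlier stage of that library as a whole is argued against by its cell cycle score, which lay -0.20 of the way (-0.34 to -0.060) toward the day 11 females, and by its epithelial (-0.60), smooth muscle (-1.41) and hypoxia (-1.15) scores, which lay on the far side, and its ASTL (14.58 on the log2 scale) and CPA1 (8.82) levels exceeded those of every day 11 library (at most 11.33 and 4.44). Other values went with an earlier stage: of the 11 lists called between the days, leukocytes (0.90 of the way), stromal fibroblasts (1.03) and angiogenic signalling (0.60) lay nearer day 11, as did liver and yolk sac genes (1.30), its score on the first component of all tested genes was -16.9 (against -46.3 to -32.3 in the rest of its group), and median ASTL was higher at day 11 (9.84 and 9.99 in females and males, against 6.20 and 4.74). What sets these genes apart between embryos stays open, and the design names no biological group within which it could be tested.

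Thrombocyte genes were higher in males, with a list score difference of 0.15 ± 0.04 (log2, SE). Gene dose on chromosome Z is argued against, since 0 tested members lie there. More blood of every kind is argued against by the erythroid score, which differed by -0.13 (-0.30 to 0.046), and the leukocyte score (-0.018 ± 0.068, SE). The erythroid score includes HBZ, itself called lower in males, so it does not measure red-cell content alone. Permuting the sex labels within days gave an adjusted p of 0.00644 over the 23 lists, with epithelial and hypoxia genes also below the threshold (0.0472 each, -0.14 and -0.052). The number of list calls itself does not set the sexes apart, since permuted labels gave at least 4 in most splits, and the list's call was lost with an estimated correlation over all genes (adjusted p = 0.791) but not over autosomal genes (adjusted p = 0.0115). A sex difference in thrombocyte number or content may be involved, as a hypothesis.

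Each count was set against 100 splits of the libraries, the real one included, with day labels permuted within sexes or sex labels within days. For the averaged day contrast 1 split, the real one, gave 9544 genes or more (highest other 2). The same held in females (1 split, 7250 against 1) and in males (1 split, 7573 against 4185). It also held for the male-female correlation (1 split, 0.902 against 0.518) and for sex at day 15 (1 split, 556 against 200). Chance is unlikely for these, but 1 in 100 is the least such splits can give, without adjustment over the counts. For the 11 day lists 3 splits gave as many (highest other 11), and for the averaged sex difference 2 splits (769 against 1622). For its autosomal part there were 2 splits (192 against 1548), for sex at day 11 3 (552 against 5301) and for the interaction 2 (4 against 3780). Such splits were rare, but without adjustment over the counts compared they make chance less likely and do not exclude it. Permuting sex labels also removes the sex difference itself, so these splits do not test the interaction alone. The splits with several times the real count point to a structure among the libraries. At day 11 libraries differed with embryo number, which 5103 genes followed. Of 100 orders of the numbers within sex and day, 1, the real one, gave as many (highest other 4523). This makes chance less likely for that count but does not exclude it, since 1 in 100 is the least such a test can give. Whether embryo number accounts for those splits stays open, since splits whose mean embryo numbers at day 11 differed by -20.4, 16 and 13.8 gave 5301, 0 and 2025 genes there. What lies behind the embryo numbers, such as an order of collection or processing, is not given in the sources used here. Chance cannot be excluded for the 4 lists called between the sexes (78 splits, highest other 11) or the 2 called for the interaction (95 splits, highest other 11).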

How the results depend on the processing

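The settings with a pseudocount of 1 or 0.01, no scaling, quality weights, residual components, short gene models left out, no trend, replicate 83 left out, embryo number as a covariate and autosomal lists were chosen after seeing the data. Over 19 settings, 2225 of 2292 results for named genes kept their direction and side of the threshold, 64 lost the call, 1 (HBAD) gained it and 2 reversed. The reversals were HBA1 (0.86) and HBAD (0.79) with the erythroid score as a covariate, a score that includes the globins that fell; 6520 genes then differed between the days, 6001 of them among the 9544. No paired analysis was possible because all embryo numbers differ. DESeq2, voom weights and svaseq, chosen for counts, were not run on FPKM.

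A threshold of 1.5-fold left 1439 genes for the averaged day contrast, 1149 in males, 934 in females, 151, 118 and 106 for sex (averaged, day 11, day 15), 0 autosomal genes and 1 interaction gene, as its stricter criterion does by construction; 51.0% of the averaged sex calls were then higher in males, against 70.2%, and 37.3% and 30.2% of those at days 11 and 15, against 73.0% and 73.9%. At an adjusted p below 0.01, 79 autosomal genes were left. With 2 residual components as covariates, which lower the residual spread by construction, 1221 genes (54.8% higher in males) and 591 autosomal genes differed between the sexes. The interaction gave 8 genes without a filter or with a pseudocount of 1, and 2 without the shallowest libraries; the cause was not tested. The Z median was 0.25 without a filter and 0.38 with a pseudocount of 1, but 0.49 with a pseudocount of 0.01 and 0.49 at a mean of at least 2. A larger pseudocount lowers the differences of genes with low values by construction. The cause of the change without a filter was not tested. The W median, -5.18, depends on the floor that male values meet: it was -1.82 without a filter, -5.53 at 1 FPKM or more, -9.36 at a mean of at least 2, -2.48 and -8.45 with pseudocounts of 1 and 0.01, and -5.66 without short gene models. With haemoglobin and mitochondrial genes left out, the W share was 0.352%. The first component of all tested genes held 29.3% and followed day. The day lists numbered 1 with an estimated correlation and 22 by fry, the sex lists 0 with an estimated correlation, 3 by fry and 11 over autosomal genes (thrombocytes alone with an estimated correlation there, adjusted p = 0.0115), and the interaction lists 0 with an estimated correlation, 0 by fry and 2 over autosomal genes (adjusted p = 0.919 and 0.945 with an estimated correlation there). No scaling moved the median of all genes by over 0.1. Autosomal sex differences were 99 higher and 92 lower with factors from autosomal genes, against 64 and 128. At these depths and group sizes 49.3% of simulated 1.5-fold interactions were called; depth itself was not varied in the simulation.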

Other observations

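The tests of genes on chromosome Z were chosen only after the results were seen, and the glucocorticoid list was written after a first look at the data but before its test.

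Genes higher in females clustered on chromosome Z between 25 and 30 Mb (GRCg6a), where the median male against female difference of the 40 tested genes was 0.012, against 0.34 to 0.80 in the other 5 Mb bins. The cluster included ENSGALG00000051419 (27317307 to 27383989) at -7.81 ± 0.16 and ENSGALG00000050012 (27177112 to 27307449) at -5.07 ± 0.11 (log2, SE), whose sizes depend on the floor of male values. DMRT1, the Z-linked gene of male sex determination (25949442 to 26005324), was also higher in females, by -0.73 ± 0.19 (adjusted p = 0.0124). Its mean level was low (-0.84 on the log2 scale), where the pseudocount weighs on the fold change. With a pseudocount of 0.01 DMRT1 stood at -0.87 ± 0.28 and was not called (adjusted p = 0.0739, range over the settings tried 0.00393 to 1). Genes higher in females made up 12 of 40 in that segment and 11 of 636 elsewhere (two-sided Fisher's exact p = 2.82e-10, for a segment chosen after its values were seen). Of the 11, 6 lie in the adjoining 20 to 25 Mb bin of 68 tested genes, so the edge of the cluster is not sharply placed. Neighbouring genes are not independent, so the p overstates the evidence. Regional regulation of this segment in females is a candidate explanation, as a hypothesis; the chicken Z chromosome is known to hold a region transcribed in females near DMRT1.

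FKBP5, a glucocorticoid-induced gene, rose by 2.48 ± 0.12 between days 11 and 15, and SGK1, another, by 1.30 ± 0.09. This led to the hypothesis that glucocorticoid signalling may be higher at day 15. In a list of glucocorticoid-responsive genes without these 2, 14 of 24 tested members were higher at day 15, 5 lower and 5 not called, with a median of 0.35. The camera p was 0.00479 at the preset correlation and 0.0439 with an estimated one, for a single list and without adjustment. BCL6 rose by 1.25 ± 0.07, PDK4 by 1.23 ± 0.11 and KLF9 by 0.99 ± 0.13, whereas GLUL changed by -0.92 ± 0.09. Many of these genes respond to other signals as well, and the membranes' hormone levels were not analysed here.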
